A study of Homo sapiens with 6 samples.

How the data were processed

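RNA from MCF7 cells, an estrogen receptor-positive human breast cancer line of luminal type, was measured on 6 Affymetrix arrays, 3 of wild-type cells and 3 of cells in which MLL3 (gene symbol KMT2C) had been deleted with a lentiviral CRISPR vector. Per the labels' protocols, the cells grew in DMEM with 10% fetal bovine serum, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 800 ng of it. The labels call the samples of each genotype biological replicates. They do not say whether these came from separate cultures or whether the knockout cells are a clone or a pool, so p-values measure the spread between these samples.

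The authors deposited 1 table of log2 signals, 1 column per array. Affymetrix Expression Console is the tool named in the submitters' processing notes. The algorithm, its version and the annotation are not given in the sources used here. The log2 scale was read from the values, which ran from 1.28 to 14.0. The array medians lay within 3.92 to 3.95, and no further normalisation was applied. No genome build was named, so no coordinates are given.

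The table held 53617 probe sets. The platform annotation gave 16098 of them 1 gene symbol and 0 of them several, and 37519 were unnamed here, which does not mean that they lie outside genes. Symbols were brought up to date through gene identifiers in the RefSeq gene table of assembly GRCh38.p14, to which all 14884 genes matched. The same table was used for which genes neighbour each other. A gene was represented by its probe set with the highest mean over the 6 arrays, a choice blind to genotype, which mattered for the 779 genes with more than 1. No control probe sets could be recognised in the table, so RNA integrity was not assessed from 3' and 5' probes. For arrays the number of samples limits the precision.

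The knockout was compared with the wild type for each of the 14884 genes with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, with no covariate and no filter on dim genes. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The count of genes changed at least 2-fold was kept beside the count by test. Values are given as mean ± SD of log2 signals, and changes as the knockout mean minus the wild-type mean with the limma standard error (SE). Single measures such as array medians were compared by exact permutation tests, which with 3 arrays against 3 cannot give a two-sided p below 0.1.

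A total of 32 gene lists were fixed before the data were examined. They cover the KMT2C complex, estrogen response, luminal, basal, junction and mesenchymal identity, signalling pathways, metabolism, the cell cycle, DNA repair, stress, apoptosis, stem and progenitor genes, and markers of fibroblasts, leukocytes and endothelium. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The same test with a correlation estimated from the residuals and limma's fry served as alternatives. Members were also tested gene by gene, adjusted over all genes and adjusted over the list alone. Between 26.5% and 94.1% of a list's members had a named probe set, and 24 lists had under 80%.

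The genes named were chosen by a rule also fixed before the data were examined. It took KMT2C; up to 12 genes per direction past the threshold whose groups did not overlap and whose mean in the higher group exceeded the median level of all genes (5.19); up to 4 members of each list with the smallest adjusted p; and ESR1, PGR, GATA3, FOXA1, KMT2D, KDM6A, HIF1A, CDH1 and VIM. HIF1A and CDH1 had no named probe set here and were not analysed. Other genes are said to have been chosen after their values were seen.

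The alternatives were each array left out in turn, a block for the replicate number, 3 normalisations between arrays, filters on dim genes, the mean of a gene's probe sets, every probe set tested on its own, a variance trend with robust estimation, array weights, and other thresholds. A fit of the 11916 protein-coding genes alone was added after the data had been seen. The fit was tested on simulated data for this comparison, with 14884 genes of which 200 changed. It recovered 50.1% of genes changed by 0.5 on the log2 scale, 86.0% of those changed by 1 and 99.4% of those changed by 2, with 4.39% of calls false. With 200 changed genes the Benjamini-Hochberg cutoff is looser than with the 19 called in the data. The recovery may therefore be overstated for this comparison. A simulated shift of 0.5 in the interferon list was called in 20 of 20 runs, and 1 of 620 tests of other lists was called. Genes were simulated independently of each other, whereas the correlation estimated for the interferon list in the data was 0.249. These runs therefore do not show how often camera calls lists of correlated genes by mistake. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.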

Results

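MLL3, encoded by KMT2C, is a histone H3 lysine 4 methyltransferase that acts at enhancers, and the study asked what its loss does to tumour cells. Transcripts of MCF7 cells were measured on 3 arrays of wild-type cells and 3 arrays of MLL3 knockout cells, with 14884 named genes on each array. The median log2 signal over all probe sets was 3.94, 3.92 and 3.94 in the wild-type arrays and 3.95, 3.94 and 3.94 in the knockout arrays. An exact permutation test of these medians between the groups gave a two-sided p of 0.6 (n = 3 per group). Correlations across the 14884 genes, which are not independent replicates, were 0.992 to 0.994 among wild-type arrays, 0.994 to 0.995 among knockout arrays and 0.990 to 0.994 between the groups. The first principal component carried 32.3% of the variance and separated the genotypes (exact permutation p = 0.1, the smallest that 3 arrays against 3 allow). Wild-type replicate 1 lay farthest out on it, at −18.1, with the other wild-type arrays at −5.72 and −5.75.

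The transcript of the targeted gene was lower in all 3 knockout arrays than in any wild-type array. KMT2C had a log2 signal of 9.14 ± 0.08 (SD, n = 3) in wild-type cells and 8.72 ± 0.03 (SD, n = 3) in knockout cells, a difference of −0.42 (SE 0.08, 95% interval −0.60 to −0.23) that left 74.99% of the wild-type level. The wild-type arrays gave 9.06, 9.14 and 9.22, and the knockout arrays 8.69, 8.72 and 8.76. Over all genes the limma adjusted p was 0.114, short of the threshold. Adjusted over the list alone, among 14 measured of 17 subunits of the KMT2C and related complexes, KMT2C was the 1 gene that passed (limma adjusted p = 0.0106). The 14 subunits together had a mean change of −0.05 (camera adjusted p = 0.499). KMT2D, the paralogous methyltransferase, had a change of −0.0028, and KDM6A, the demethylase of the same complex, of −0.09, both far from the threshold. SETD1A (−0.15), DPY30 (0.12) and CXXC1 (−0.16) did not pass either. The call on KMT2C depended on the genes tested and on the variance model: its limma adjusted p was 0.0379 among genes above the median level and 0.0119 over all genes with a variance trend and robust estimation together. The 1 probe set reports the abundance of the transcript, and where it lies relative to the CRISPR cut is not given in the sources used here.

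A small set of genes passed the test between MLL3 knockout and wild-type cells. Between the genotypes 12 genes rose and 7 fell (limma, adjusted p from 0.0249 to 0.0460), and 5 of the former and 3 of the latter changed at least 2-fold. In all 19 the 3 knockout arrays lay on one side of the 3 wild-type arrays. Over all 14884 genes the groups did not overlap for 2274, or 15.3%, where chance gives 10%. At an unadjusted p under 0.05 there were 757 higher and 608 lower genes, 1365 in all, against 744.2 by chance.

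The largest rises were in ART4, which carries the Dombrock blood group antigen, and MC4R, the melanocortin 4 receptor. ART4 went from 5.20 ± 0.38 to 7.05 ± 0.25 (SD, n = 3), a rise of 1.85 (SE 0.19, limma adjusted p = 0.0249), and MC4R from 4.39 ± 0.29 to 6.14 ± 0.30, a rise of 1.76 (SE 0.18). SYNPO2, an actin-binding protein, rose by 1.73 (SE 0.20). HIPK2, a stress-responsive serine/threonine kinase, rose by 1.10 (SE 0.10), and NRP1, a co-receptor for semaphorins and VEGF, by 1.07 (SE 0.13). PAPSS2, which makes the sulfate donor for sulfotransferases, rose by 0.97 (SE 0.10), as did IFIT5, an interferon-induced RNA-binding protein, by 0.97 (SE 0.11). Smaller rises were seen in CCDC83 (0.91), the calcium-binding protein gene NECAB1 (0.85), the homeobox gene PBX3 (0.80), the glutathione transferase gene GSTM3 (0.68) and MGP (0.67), an inhibitor of calcification. MGP was the brightest of the 12, at 11.6 ± 0.08 in knockout cells.

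The largest fall was in CEACAM5, the carcinoembryonic antigen, a cell-surface adhesion molecule. It went from 8.33 ± 0.75 to 5.59 ± 0.52 (SD, n = 3), a change of −2.74 (SE 0.37, limma adjusted p = 0.0460) or 6.66-fold. SCIN, which severs actin filaments, changed by −2.16 (SE 0.26), and CAPN9, a calpain protease of the digestive tract, by −1.40 (SE 0.14). DUSP4, a phosphatase that inactivates ERK, changed by −0.99 (SE 0.13), S100P, a calcium-binding protein, by −0.75 (SE 0.10), and FGF13, an intracellular fibroblast growth factor homologue, by −0.75 (SE 0.10). ASPH, an aspartyl hydroxylase, also fell, by 0.85 (SE 0.11). It lay outside the rule for named genes because both groups were below the median level, and it was named after its values were seen.

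The number of changed genes depended on which arrays were kept. It was 0 without wild-type replicate 1 or knockout replicate 1 (limma, 1460 and 1078 at an unadjusted p under 0.05). It was 1 without knockout replicate 2, 4 without wild-type replicate 2, 5 without wild-type replicate 3 and 13 without knockout replicate 3. The count changed at least 2-fold was 0, 0, 1, 4, 4 and 12 in the same order. With limma's treat, which tested for a change beyond 1.2-fold, 0 genes passed (203 at an unadjusted p under 0.05). The number of changed genes ran from 0 with every probe set tested on its own (3650 at an unadjusted p under 0.05) to 123 with a variance trend and robust estimation together, and the division was 13 higher and 12 lower with median centring and 12 and 4 with 75th percentile centring.

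**Figure D1:**
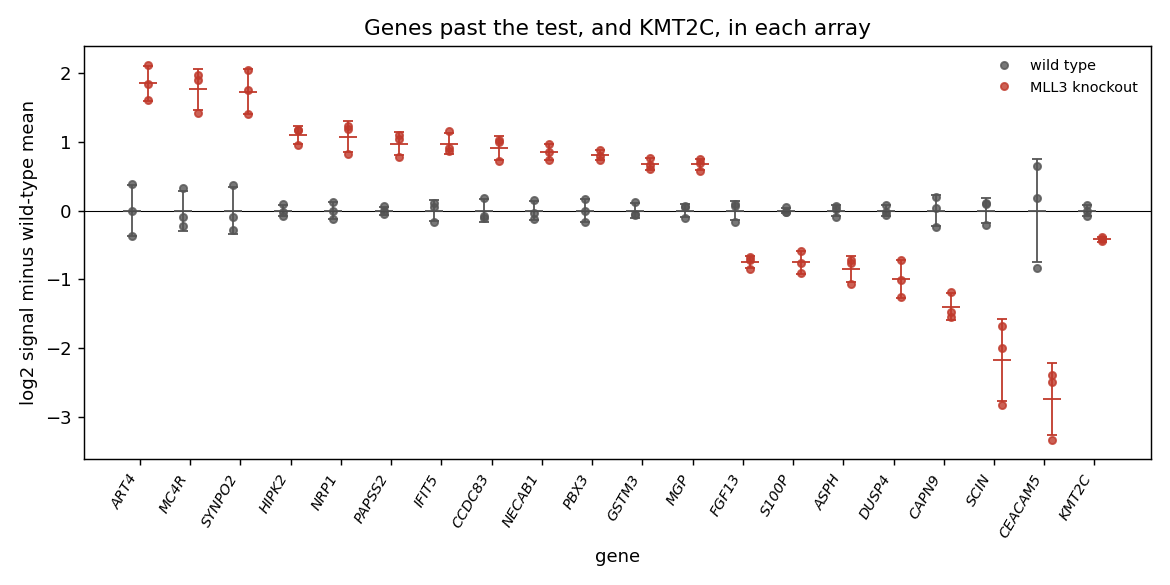
Log2 signal of the 19 changed genes and of KMT2C in each array, minus the wild-type mean of the gene (y axis), with wild-type arrays in grey and MLL3 knockout arrays in red; points are arrays, and bars are the mean ± SD (n = 3). The groups do not overlap for any gene shown, from ART4 at 1.85 to CEACAM5 at −2.74.

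Type I interferon-stimulated genes were higher in the knockout cells as a group. Of 24 measured of 34 members, 22 were higher, with a mean change of 0.54 (SD over members 0.39) and a median of 0.56 (camera adjusted p = 4.43e-16). The call was lost when the correlation between members was taken from the data (adjusted p = 0.545 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 13 rose (limma). The largest changes were in IFIT1 (1.51, limma adjusted p over all genes 0.0533) and SAMD9 (1.13, 0.0729), 2 interferon-induced antiviral factors. IFIT3 (0.99, 0.0852) and the ubiquitin-like modifier ISG15 (0.82, 0.0719) also passed over the list alone. IFIT5, which rose over all genes, is not a member. The list mean relative to the wild-type mean was −0.24, 0.10 and 0.14 in the wild-type arrays and 0.58, 0.46 and 0.59 in the knockout arrays. The list of interferon-gamma response and antigen presentation genes had a mean change of 0.11 over 14 measured of 32 members (camera adjusted p = 0.0591). It passed with 2 of the 6 arrays left out in turn (adjusted p = 0.0211 without wild-type replicate 2, 0.0239 without knockout replicate 1, up to 0.364) and in 4 of 12 other alternatives (8.50e-04 to 0.597). In it 0 members passed over all genes and 3 adjusted over the list alone: the kinase JAK2 (0.43), the peptide-loading factor TAPBP (0.37) and the class I light chain B2M (0.38). A second, dimmer B2M probe set had a change of 0.05, whereas the other TAPBP probe sets were at 0.37 to 0.39. GBP4, an interferon-induced GTPase, had a change of −0.34. NF-kappaB targets had a mean of 0.10 over 14 of 23 members (camera adjusted p = 0.107), with NFKB2 at 0.27, IER3 at 0.26, RELB at 0.21 and NFKB1 at 0.19, none of which passed. That list passed without knockout replicate 1 (mean 0.13, camera adjusted p = 0.0239) and among genes above the median level (mean 0.16, 0.0130), with adjusted p up to 0.545 in the other settings.

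**Figure D2:**
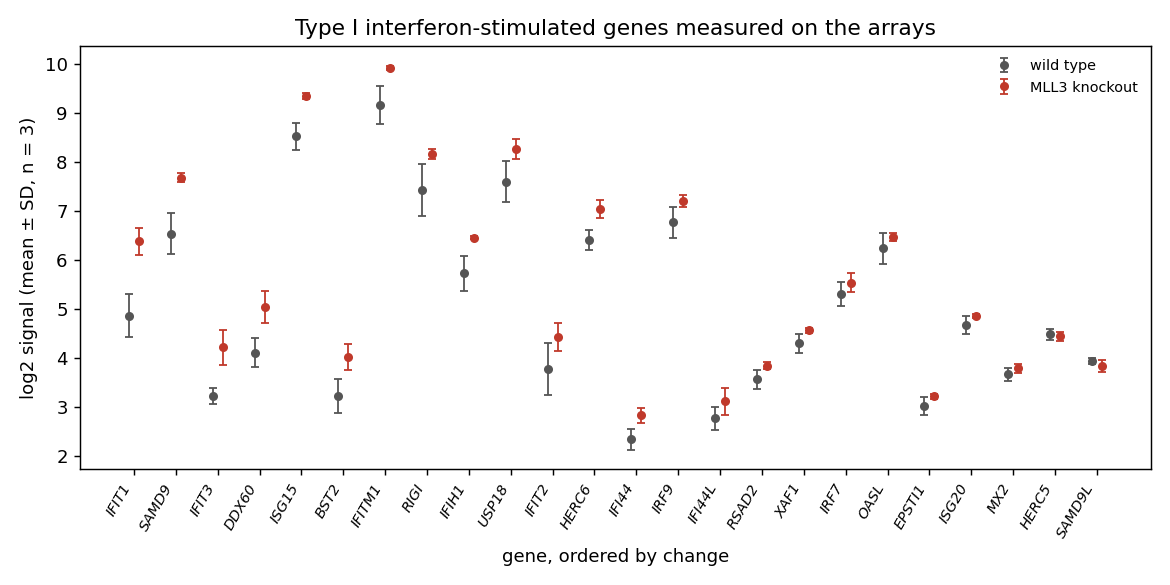
Log2 signal (y axis) of the 24 measured type I interferon-stimulated genes, ordered by change (x axis), as mean ± SD (n = 3) in wild-type cells (grey) and MLL3 knockout cells (red). The knockout mean is higher for 22 of them, by 1.51 for IFIT1.

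Genes of luminal breast identity were lower as a group, by a smaller amount. Of 19 measured of 23 members 14 were lower, with a mean change of −0.14 (SD over members 0.29) and a median of −0.09 (camera adjusted p = 0.0107; adjusted p = 0.545 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 2 fell (limma): SPDEF, an ETS factor of luminal cells, at −1.11 (SE 0.20), and AGR2, a disulfide isomerase of secretory epithelium, at −0.45 (SE 0.08). MLPH (−0.27) and CD24 (−0.30) did not pass. The list's keratin genes, named after their values were seen, had changes of 0.14 (KRT18), 0.13 (KRT8), −0.01 (KRT19) and −0.09 (KRT7), and none passed. The central luminal regulators stayed within 0.20 of the wild-type level on the log2 scale: ESR1, the estrogen receptor, had a change of −0.04, GATA3 of −0.06 and FOXA1 of −0.20 (limma adjusted p = 0.929, 0.877 and 0.506). PGR, the progesterone receptor, had a change of −0.18 (limma adjusted p = 0.746). The list's call was lost without wild-type replicate 3 (mean −0.12, camera adjusted p = 0.0821).

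Estrogen-induced genes had members on either side, 11 higher and 11 lower of 22 measured of 30, with a mean change of −0.06 (camera adjusted p = 0.594). None passed over all genes, and adjusted over the list alone 3 rose and 6 fell (limma). Among them were the chemokine gene CXCL12 (−0.86), STC2 (−0.65), the carbonic anhydrase gene CA12 (0.48) and MYBL1 (0.33). Basal and myoepithelial genes had a mean change of 0.0059 over 10 measured of 22 (camera adjusted p = 0.918), with EGFR at 0.34, KRT16 at 0.30, SOX10 at −0.18 and KRT5 at −0.14, none past the threshold. Epithelial junction genes had a mean of −0.02 over 23 of 28 (0.625). Adjusted over the list alone 2 of these passed, the desmosomal cadherin DSC2 at −1.19 and the claudin CLDN1 at 0.99, against 0 over all genes. MARVELD3 (−0.21) and GRHL1 (−0.22) did not pass. Mesenchymal genes had a mean of −0.02 over 16 of 25 (camera adjusted p = 0.792), and VIM (−0.28), S100A4 (0.36), IGFBP7 (−0.31) and AXL (−0.13) did not pass.

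Stem and progenitor genes were lower as a group, with 9 of 12 measured of 18 members lower and a mean change of −0.23 (SD over members 0.29, camera adjusted p = 0.0113; adjusted p = 0.545 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The members with the smallest limma p were the transcription factor genes SOX4 (−0.35), KLF4 (−0.27) and SOX2 (−1.02) and the surface glycoprotein gene CD24 (−0.30), which the luminal list also holds. A lower level of a member such as CD24 need not mean a less stem-like state, so the list mean does not measure one. SOX2 varied between the wild-type arrays, at 6.95, 4.97 and 5.46, and its change was −0.44 without wild-type replicate 1. Without wild-type replicate 1 the list had a mean change of −0.12 and the call was lost (camera adjusted p = 0.211).

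**Figure D3:**
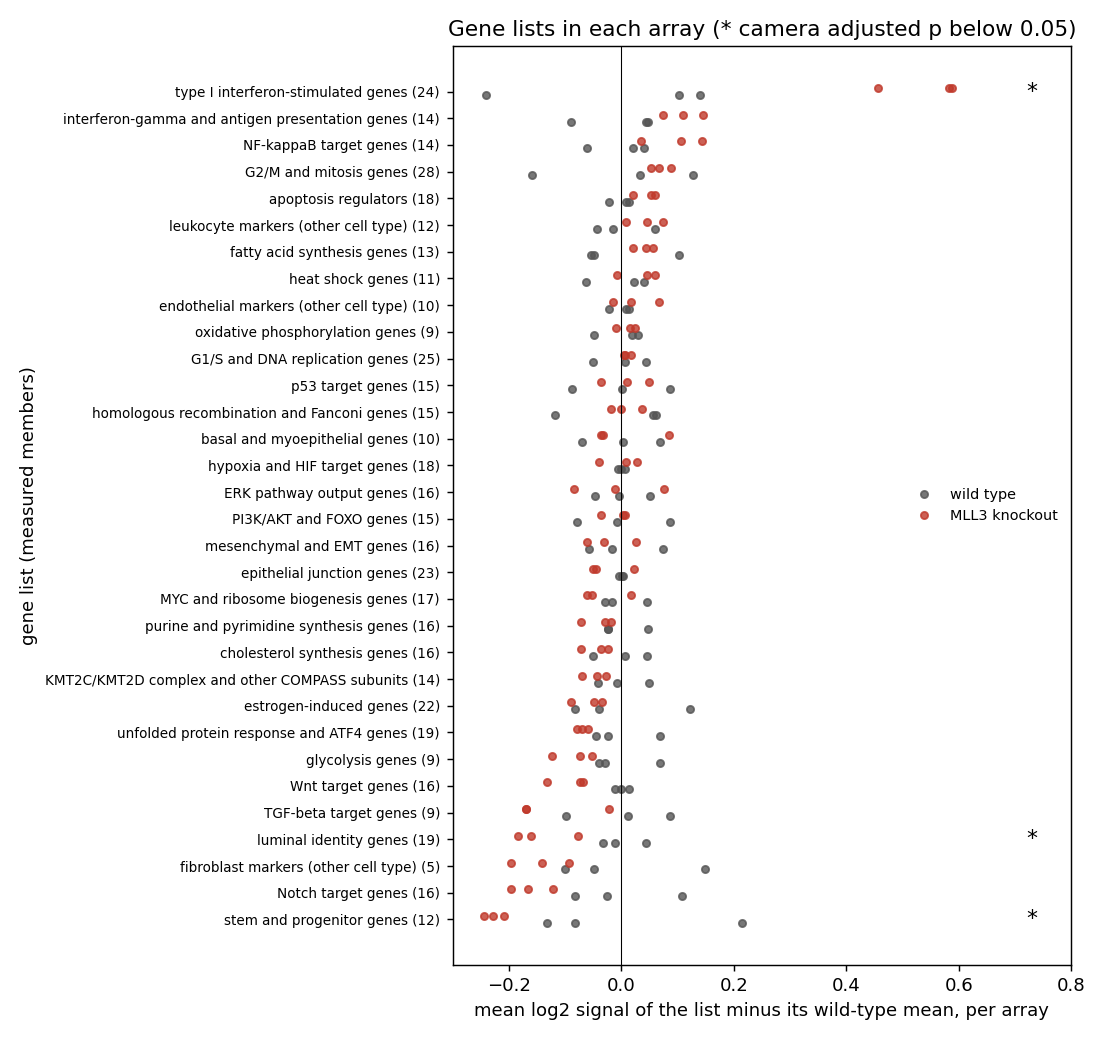
Mean log2 signal of each of the 32 gene lists in each array, minus the list's wild-type mean (x axis), with wild-type arrays in grey, MLL3 knockout arrays in red and the number of measured members in parentheses (y axis). Points are arrays, n = 3 per group; an asterisk marks the 3 lists with a camera adjusted p below 0.05, of which the interferon list has a mean change of 0.54.

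Developmental signalling lists did not pass with all 6 arrays. The Notch list holds pathway receptors, ligands and a coactivator besides target genes, so its mean is not one of targets alone. It had a mean change of −0.16 over 16 measured of 17 (camera adjusted p = 0.113). It passed without wild-type replicate 3 (mean −0.20, camera adjusted p = 0.0275), with an adjusted p up to 0.545 in the other settings. Its member HEY2, a Notch-induced repressor, had the largest change at −1.74 (SE 0.28). HEY2 was the 1 member to pass adjusted over the list alone, against 0 over all genes (its limma adjusted p = 0.0690). The coactivator gene MAML2 (−0.32), the receptor gene NOTCH1 (−0.20) and the ligand gene DLL1 (−0.19) did not pass. Wnt targets had a mean of −0.09 over 16 of 18 (camera adjusted p = 0.153), with APCDD1 at −0.34, ZNRF3 at −0.33, RNF43 at −0.29 and CCND1 at −0.19 and 0 members past either threshold. TGF-beta targets had a mean of −0.12 over 9 of 18 (camera adjusted p = 0.241). BAMBI, a TGF-beta pseudoreceptor, had a change of −0.82 and was the 1 member to pass adjusted over the list alone, against 0 over all genes, while LTBP2 (−0.14), SKI (−0.13) and CCN2 (−0.09) did not. ERK output genes had a mean of −0.0070 over 16 of 20 (camera adjusted p = 0.938). DUSP4 fell over all genes, and adjusted over the list alone it was joined by DUSP5, a nuclear ERK phosphatase, at 0.48. A second, dimmer DUSP5 probe set had a change of 0.15. EPHA4 (0.53) did not pass. The PI3K and FOXO list had a mean of −0.0087 over 15 of 21 (0.918). Adjusted over the list alone 4 members passed, SESN3 (0.68), IGF1R (0.34), TXNIP (−0.52) and BCL6 (−0.44), against 0 over all genes.

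Metabolic lists did not pass. Glycolysis genes had a mean of −0.08 over 9 measured of 21 (camera adjusted p = 0.625). Adjusted over the list alone hexokinase 2, HK2, fell by 0.89 and TPI1 rose by 0.31, against 0 members over all genes, and HK1 (−0.14) and LDHB (0.14) did not pass. Hypoxia targets had a mean of −0.0015 over 18 of 27 (0.778). Adjusted over the list alone 2 rose and 3 fell, against 0 over all genes, among them LOXL2 (0.88), CA12 (0.48), DDIT4 (−0.43) and HILPDA (−0.39). Oxidative phosphorylation genes had a mean of 0.01 over 9 of 34 (0.991), with COX6C at 0.24, UQCRC2 at −0.08, UQCRC1 at −0.08 and COX5B at 0.09. Cholesterol synthesis genes had a mean of −0.04 over 16 of 24 (0.259), with MVD at −0.25 and STARD4 at 0.27, PMVK at −0.16 and TM7SF2 at −0.14. Fatty acid synthesis genes had a mean of 0.04 over 13 of 15 (0.801), with FADS1 at 0.29, THRSP at 0.63, FASN at −0.27 and ACACA at −0.22. Purine and pyrimidine synthesis genes had a mean of −0.04 over 16 of 22 (0.499), with TYMS at 0.22, DHODH at −0.25, IMPDH1 at −0.20 and IMPDH2 at −0.18. In these last 4 lists 0 members passed over all genes or adjusted over the list alone.

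Lists of proliferation and stress did not pass with all 6 arrays. Mitotic genes had a mean of 0.07 over 28 measured of 34, 22 of them higher (camera adjusted p = 0.138), with BIRC5 at 0.27, CCNB1 at 0.20, KIF23 at 0.17 and KIF11 at −0.15. The mitotic list passed without wild-type replicate 2 (mean 0.13, camera adjusted p = 8.98e-04) and had a mean of −0.01 without wild-type replicate 1 (0.821). Genes of G1/S and DNA replication had a mean of 0.0090 over 25 of 35 (0.960), with TYMS at 0.22, MCM5 at −0.22, CLSPN at 0.18 and MCM6 at −0.14. The homologous recombination and Fanconi list had a mean of 0.0060 over 15 of 32 (0.918), with RAD54L at 0.17, BRIP1 at 0.14, ATR at −0.12 and NBN at 0.11. MYC and ribosome biogenesis genes had a mean of −0.03 over 17 of 31 (0.499), with BOP1 at −0.13, FBL at −0.12, ODC1 at 0.13 and NOLC1 at −0.10. Targets of p53 had a mean of 0.0071 over 15 of 28 (0.918), with TP53I3 at 0.31, GDF15 at −0.47, PLK2 at 0.41 and TP53INP1 at −0.21. Apoptosis regulators had a mean of 0.04 over 18 of 26 (0.499), with BOK at 0.26, BCL2L11 at 0.38, BIK at −0.31 and BID at 0.14. Heat shock genes had a mean of 0.03 over 11 of 21 (0.973), with HSPB8 at 0.49, HSPA1A at −0.18, HSPA1B at −0.15 and BAG3 at 0.21. None of the members of these 7 lists passed over all genes or adjusted over the list alone. Genes of the unfolded protein response and ATF4 had a mean of −0.07 over 19 of 31 (0.163). DDIT4, an inhibitor of mTORC1, was the 1 of these to pass adjusted over the list alone, against 0 over all genes, and PHGDH (−0.33), SEL1L (−0.19) and CRELD2 (0.14) did not.

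No list of markers of cell types other than breast epithelium passed. Leukocyte markers had a mean change of 0.04 over 12 measured of 20 (camera adjusted p = 0.580), endothelial markers of 0.02 over 10 of 14 (0.852) and fibroblast markers of −0.14 over 5 of 16 (0.138). Adjusted over the list alone and over all genes 0 of these markers passed, among them TYROBP (0.12), CD4 (0.13), NKG7 (0.09), CD8A (0.06), ESAM (−0.29), ENG (0.19), TIE1 (0.20), VWF (0.17), LUM (−0.29), FBN1 (−0.20), THY1 (−0.08) and DCN (−0.06). None of the 32 lists passed with an estimated correlation (2 at an unadjusted p under 0.05) or with fry (4 at an unadjusted p under 0.05). The mean and the median had opposite signs for the basal, heat shock, oxidative phosphorylation, homologous recombination and PI3K lists, and camera pointed up for the ERK list, whose mean and median were below 0.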

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

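The fit of protein-coding genes alone was chosen after the data had been seen; the other settings were planned. All 19 changed genes kept their direction in each setting that tested them. As their groups did not overlap, leaving out 1 array could not have reversed it. Filters on dim genes and the variance trend leave the change itself as it was. With 1 array left out, 0 to 10 of the 19 kept the call. The count of changed genes was 0 with every probe set tested (limma, 3650 at an unadjusted p under 0.05), 0 at an adjusted p under 0.01 and 80 at one under 0.10. It was 86 among genes above the median level, 37 above the 25th percentile, 123 with a variance trend and robust estimation together, 42 with array weights (lowest weight 0.594, wild-type replicate 1) and 49 among protein-coding genes, and it ran from 0 (without wild-type replicate 1 or knockout replicate 1) to 13 with 1 array left out. With limma's treat, which tested for a change beyond 1.2-fold, 0 genes passed (203 at an unadjusted p under 0.05). The count of changed genes by size was 19 at 1.5-fold. At 2-fold it was 19 above the median level, 15 with the trend and robust estimation, 14 with weights and 16 among protein-coding genes. The 2-fold count was 0 without wild-type replicate 1 or knockout replicate 1 and 1 without knockout replicate 2. It was 4 without wild-type replicate 2 or 3 and 12 without knockout replicate 3. Fewer genes entered the filtered fits, but the cause of the different count was not tested for any setting. The count of gene lists was 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 with fry (4), 5 above the median level and from 2 to 5 with 1 array left out (5 without wild-type replicate 2 or knockout replicate 1). The interferon list passed with each array left out (camera adjusted p from 2.37e-16 to 1.15e-13, mean 0.42 to 0.61). KMT2C, at −0.42 in both, had a limma adjusted p of 0.0379 above the median level and 0.0119 with the trend and robust estimation, and a change of −0.45 to −0.37 with 1 array left out. Quantile normalisation, median centring, 75th percentile centring and the mean of probe sets gave 15, 25, 16 and 19 genes. For chromosomes the count was 0 with each of the 6 arrays left out and in the 10 other settings in which it was run. The alternative restricted by probe set suffix was not run, as the identifiers carry no suffix. No background level was used here, so the share of genes near it is unknown.

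Shared replicate numbers did not pair the arrays: the deviations of same-numbered arrays correlated at −0.010 to 0.046 and those of other pairs at −0.030 to 0.031, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block 1 gene passed (CEACAM5), also the 1 changed at least 2-fold, with 1306 genes at an unadjusted p under 0.05; the 3 lists still passed.

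No result that changed sign had passed with all 6 arrays in the setting reported, and the cause was not tested; the mitotic list, among them, passed without wild-type replicate 2 (mean 0.13, camera adjusted p = 8.98e-04). With quantile normalisation the basal list was at −0.0059 and KMT2D at 0.0058. With 75th percentile centring the hypoxia list was at 0.0035 and KMT2D at 0.0021. Above the median level the heat shock list was at −0.018, the ERK list at 0.016 and the PI3K list at 0.0019. Above the 25th percentile the hypoxia list was at 4.41e-04 and the endothelial list at −0.0050. With the mean of probe sets LTBP2 was at 0.040. With array weights the hypoxia list was at 0.0020 and the homologous recombination list at −0.013. With 1 array left out the ranges were −0.099 to 0.0036 for the estrogen list, −0.034 to 0.040 for the basal list, −0.051 to 0.015 for the mesenchymal list, −0.016 to 0.031 for the G1/S list, −0.010 to 0.13 for the mitotic list, −0.053 to 0.037 for the homologous recombination list and −0.016 to 0.018 for the hypoxia list. They were −0.037 to 0.051 for the p53 list, −0.048 to 0.032 for the ERK list, −0.014 to 0.025 for the oxidative phosphorylation list, −0.048 to 0.034 for the PI3K list, −0.048 to 0.041 for KMT2D, −0.17 to 0.014 for CCN2, −0.050 to 0.14 for CD8A and −0.070 to 0.0020 for ESR1.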

Other observations

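The tests of normalisation, leukocyte RNA, the vector and adjacent genes were chosen only after the result was seen. So were the other splits for all changed genes and for the unadjusted count. The expressed neighbours and the remaining splits were set before it was seen. The second interferon list was written before its own values were seen, to follow up the rise of the first list. Beyond the 19 changed genes, 61 more lay at a limma adjusted p between 0.05 and 0.10, and the genes named in this paragraph were chosen after their values were seen. Among receptors, GPER1, a G protein-coupled estrogen receptor, had a change of 1.22 (SE 0.19, limma adjusted p = 0.0617) and CALCR, the calcitonin receptor, of 1.11 (SE 0.17, 0.0565). AHR, the aryl hydrocarbon receptor, had a change of −0.80 (SE 0.11, limma adjusted p = 0.0533). The adhesion gene AMIGO2 had a change of 1.64 (SE 0.29, 0.0849), the mucin-like gene MUCL1 of −2.10 (SE 0.35, 0.0749) and the kinase gene CDK14 of −1.24 (SE 0.18, 0.0533). CEACAM6, a relative of CEACAM5, had a change of −2.25 (SE 0.58) with a limma adjusted p of 0.2501, at 7.41 ± 1.37 in wild-type cells and 5.17 ± 0.51 in knockout cells (SD, n = 3).

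The rise of the interferon list was kept under 3 further normalisations between arrays, with a lowest mean change of 0.534, against 0.54 as deposited. The deposited arrays were already aligned, with medians within 3.92 to 3.95, so these normalisations could move the list little. They do not test the original processing. Leukocyte RNA would bring leukocyte markers, whose mean change had an upper 95% bound of 0.0765 from the spread between 12 markers, and ran from 0.020 (without wild-type replicate 2) to 0.072 (without wild-type replicate 3) with 1 array left out; those markers lie low, at a median of 4.52. A second list of 41 interferon-stimulated genes, sharing none with the first, had 22 of 23 measured members higher and a mean of 0.26 (camera adjusted p = 2.64e-08), but an adjusted p of 0.482 with an estimated correlation; over all genes 0 members passed and 8 rose adjusted over the list alone. This is consistent with a wider interferon programme, of which the loss of MLL3 is a candidate cause. A response to the lentiviral vector itself cannot be told apart from it, since 0 arrays here are labelled as cells given a vector without an MLL3 guide, and the labels do not say whether the wild-type cells received one.

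For the changed genes, a broad difference in copy number between the populations would move neighbouring genes along with them. The 20 expressed neighbours of each of the 19 genes had a mean change of 0.0263 in the gene's direction (upper 95% bound 0.0603), and 0 genes had neighbours averaging 0.2 or more. On whole chromosomes, 0 of 23 passed (camera, 1 at an unadjusted p under 0.05, smallest adjusted p 0.941). Broad copy number differences are therefore unlikely to account for the set. A gain or loss spanning only a few genes would be averaged out over 20 neighbours and was not excluded. A difference between cell populations that preceded the knockout may also account for the set, as clones were not compared here.

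Several of the strongest genes lie side by side. ART4 and MGP, both risen, are adjacent among measured genes on chromosome 12, with C12orf60 (0.58) within 3 measured genes of each, and IFIT1 and IFIT5 are adjacent on chromosome 10. For the 19 genes there was 1 such pair, and the share of 10000 random sets with as many was 0.0636. For the 80 genes at an adjusted p under 0.10 there were 10 pairs against 1.26 on average, and no random set had as many (share at most 1e-04, the smallest that 10000 sets can give). Besides the groups above, these were AGR2 (−0.45) with AHR (−0.80) and CALCR (1.11) with TFPI2 (0.74) on chromosome 7. On chromosome 8 they were NECAB1 (0.85) with C8orf88 (0.75) and PSD3 (−0.92) with SH2D4A (−0.575). Shared regulation of neighbours, or a copy number change limited to a few genes, may contribute. The test on the 19 genes did not separate the grouping from chance, and the wider set was tested after its values were seen.

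The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 19 changed genes and the highest other split 0 (1 of 10 splits as large), 8 against 0 for genes changed at least 2-fold (1 of 10), and 1365 against 725 for genes at an unadjusted p under 0.05 (1 of 10). For gene lists the real split gave 3 and another split also 3 (2 of 10 splits as large), and for chromosomes all 10 splits gave 0. The absolute mean change of the interferon list was 0.54 in the real split and at most 0.33 in the others. As each knockout array lay above each wild-type array for this list, the real split had to give the largest value. In the other splits a difference between the genotypes adds to the spread within groups, which can lower their counts of genes. Among the 37519 unnamed probe sets 0 passed (limma, 2508 at an unadjusted p under 0.05, smallest adjusted p 0.0586).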
